A study of Agrobacterium sp. CGMCC 11546 with 6 samples.

How the data were processed

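RNA levels were measured by RNA sequencing in 6 samples of Agrobacterium sp. CGMCC 11546, a soil bacterium that secretes curdlan, a gel-forming polymer of glucose. Per the labels' protocols, cells were flash frozen, RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit. The labels assign 3 libraries to 7 h of fermentation and 3 to 24 h, and describe them as biological repeats. The 6 libraries were grouped by these times. No batch, sequencing date or strand setting is given in the sources used here.

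The authors deposited 1 table per library, with a locus tag and its RPKM value (reads scaled to gene length and to library size), and replicates were not pooled, per the file headers and names. The submitters' processing notes name Bowtie 0.12.2, a short-read aligner, and HTSeq, a read counter. How ambiguous or multiply aligned reads were treated is not given in the sources used here, and neither is the reference genome. The 5472 tags are numbered in steps of 5 without a gap, and no symbol or product is paired with them. The 35 gene lists written before the data were examined, among them the curdlan synthesis genes, therefore could not be matched to tags, and no list test was run. Genes are given by tag, with at most 2 tags in each direction. Those are the 2 genes with the largest rise and the 2 with the largest fall in the main test among genes that passed the test, had a mean of at least 50 RPKM at the time with the higher level, and did not overlap between times, which 0.1 of unchanged genes do by chance. The rule fixed before the data were examined asked for 8 genes in each direction with a known name and for members of the gene lists, with 2 tags in each direction where tags have no names. Neighbours of the named tags are described without their tags and were chosen after their values were seen.

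An RPKM value is a whole number of reads divided by the gene's length and the library's total, so ratios between libraries are ratios of whole numbers. The smallest whole reads in those ratios, the gene lengths and the library totals were worked out from the deposited RPKM values. The 6 totals came out within 8e-05 of whole numbers. Reads and lengths reproduced 100% of the 27462 RPKM values above 0 within a relative tolerance of 1e-06, and 97.8% of the lengths were multiples of 3, as coding lengths are. The total of 7 h replicate 1 was chosen to make this share as large as possible, so the share is no separate check. For 11 genes read in 1 library only, 1 read was assumed and the length was solved to match. The recovered reads added up to between 99.06% and 99.57% of the totals. The remainder can come from genes whose reads share a common factor in every library. Their reads can be recovered too low, and their lengths too short, by that factor. Such a factor cancels in RPKM, so the match of the RPKM values cannot reveal it. In simulated data all 6 totals and the reads of 99.1% of 4604 genes were recovered exactly. The reads were used for depth, read shares and undetected genes, and in 1 alternative test, not in the main test. The lengths were used for the comparisons by gene length and in the fit without the length trend.

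Library totals, the read numbers by which RPKM was scaled, ranged from 2478642 to 5017833. Whether they count only reads assigned to genes was not tested. A gene with 0 reads in all 6 libraries had 0 of 19745871 reads, which allows a share of up to 1.52e-05% (3 reads). Such limits cover counting error only.

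The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(RPKM + 1) as deposited, without further scaling and without a replicate block. It used 4592 genes with a mean of at least 1 RPKM over the 6 libraries. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes, and are 24 h minus 7 h. In data simulated for this comparison over 4586 genes, 85% of 100 genes changed by 2-fold and 98% of 100 genes changed by 4-fold were called in the right direction. There, 11 of 4386 unchanged genes were called. All simulated genes had the same dispersion, 0.026, and few genes were changed. In the deposited data far more genes were called and the spread can differ from gene to gene, so these shares need not hold there.

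Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 RPKM, no filter and a minimum mean of 10 RPKM, 3 other scalings, a robust fit, the replicate number as a block, and leaving out each library in turn. The 3 scalings were an equal RPKM sum per library, a median ratio to the genes' geometric means, and quantile normalization. Negative binomial tests of whole reads were also planned should reads be recoverable. Reads were recovered, so that condition was met, but these tests were not run. Limma's voom was run on the recovered reads. This was added after seeing the data, as was a fit after removing each library's trend of level on gene length (loess, span 0.5). Recovery, shuffles and plots used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.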

Results

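Gene expression was compared between an early and a late time of curdlan fermentation, 7 h and 24 h, with 3 libraries at each time. Curdlan is a water-insoluble glucose polymer that the bacterium exports. The library totals worked out from RPKM were 2921661, 5017833 and 2478642 reads at 7 h, and 2848493, 2731699 and 3747543 at 24 h. Between 4537 and 4598 of the 5472 locus tags had a value above 0 in a library. In all 6 libraries 4497 genes had reads, and 851 genes had none. The tables pair no gene symbol or function with a tag, so the genes of curdlan synthesis were not identified here. Positions on the genome and annotations were likewise not used here.

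The transcriptome at 24 h differed from that at 7 h in most of the genes tested. Of 4592 genes, 1240 were higher and 1608 were lower at 24 h, and 1744 did not pass (limma on log2(RPKM + 1), Benjamini-Hochberg adjusted p under 0.05, n = 3 per time). By at least 2-fold, 1055 genes rose and 1289 fell. By at least 8-fold, 259 genes rose and 205 fell. A change of at least 64-fold was found in 19 genes that rose and 14 that fell, and one of at least 256-fold in 6 genes, which all rose. With libraries scaled to an equal RPKM sum, AGR8A_RS15470 and AGR8A_RS10080 also fell by over 256-fold (log2 fold changes of -8.12 and -8.10). The median change of all genes was -0.19 on the log2 scale. With libraries scaled to an equal RPKM sum this median was -0.71, and the calls split into 892 higher and 2195 lower. The median was 0.03 with median-ratio scaling and -0.06 with quantile normalization. Under the equal sum 28.9% of the calls were higher at 24 h, against 43.5% for RPKM as deposited. With median-ratio scaling rises were in the majority, with 1462 higher and 1391 lower (51.2% higher), so the balance between rises and falls depends on the scaling.

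Among the largest rises was that of AGR8A_RS23360, a gene of 1458 nt, which ranked 1 with RPKM as deposited and 1 to 3 over the 17 alternatives. Its level was 47.3 ± 4.17 RPKM at 7 h and 31714 ± 7271 RPKM at 24 h (SD, n = 3 each), a ratio of means of 669.8. The log2 fold change was 9.33 with a standard error of 0.24 (limma, adjusted p = 1.251e-06). This gene alone held 0.0069% ± 0.0006 of the reads at 7 h and 4.62% ± 1.06 at 24 h (SD, n = 3). The next tag, AGR8A_RS23365 (1965 nt), ranked 2 (2 to 4 over the alternatives) and rose from 5.29 ± 0.24 to 3051 ± 855 RPKM, with a log2 fold change of 8.88 ± 0.25 (SE; limma, adjusted p = 1.251e-06). The tag after that, a gene of 1266 nt, rose by 7.53 ± 0.38 on the log2 scale, from a mean of 2.31 to 568 RPKM (limma, adjusted p = 6.159e-06). The tags on either side of these 3 changed far less, by 0.64 ± 0.23 and 0.50 ± 0.18 (SE; limma, adjusted p = 0.040 and 0.042). A gene 2 tags before the first of the 3, also of 1965 nt, rose by 4.20 ± 0.27 (limma, adjusted p = 1.298e-05).

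Falls were led by AGR8A_RS15470 and AGR8A_RS10080, whose order was not settled: the latter fell more in 4 of the 17 alternatives, and over these the ranks were 1 to 2 and 1 to 4. AGR8A_RS15470, a gene of 1074 nt, fell from 3415 ± 162 RPKM at 7 h to 16.98 ± 3.68 RPKM at 24 h (SD, n = 3 each). The mean at 7 h was 201-fold that at 24 h, and the log2 fold change was -7.59 ± 0.21 (SE; limma, adjusted p = 1.251e-06). The tag after it fell as well, with a log2 fold change of -5.73 ± 0.27 (SE; limma, adjusted p = 5.039e-06). AGR8A_RS10080 (1362 nt) fell from 5749 ± 1575 to 33.0 ± 19.7 RPKM, with a log2 fold change of -7.57 ± 0.49 (SE; limma, adjusted p = 1.328e-05). The 2 tags before it changed by -6.27 ± 0.22 and -6.72 ± 0.22 and the tag after it by -2.93 ± 0.39 (SE), and each of these passed the test. The 4 tags were chosen to have no overlap between the 3 libraries of each time.

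**Figure D1:**
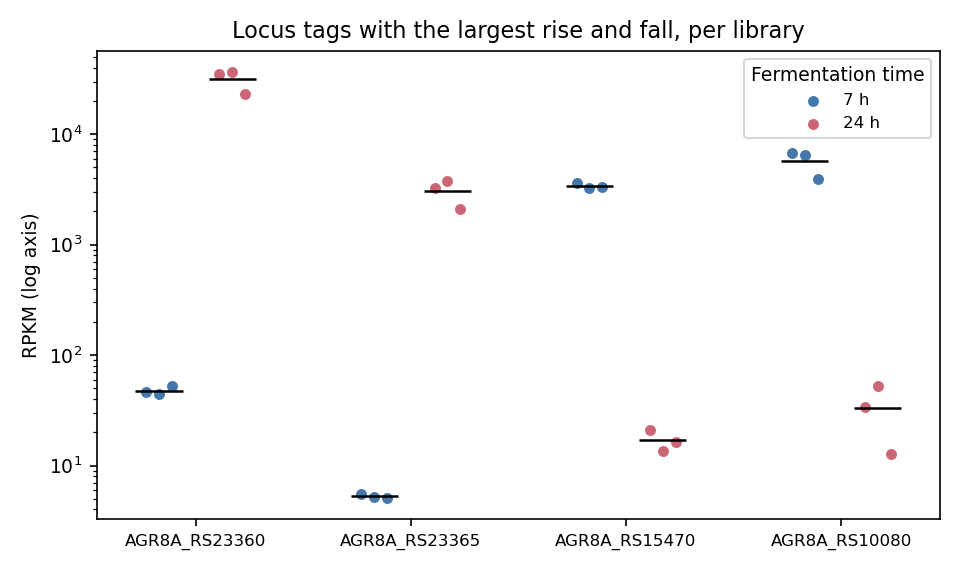
RPKM of the 4 named locus tags in each library on a log axis; points are single libraries (n = 3 per time), horizontal lines are means, and colours are the fermentation times. AGR8A_RS23360 and AGR8A_RS23365 lie higher in every 24 h library, AGR8A_RS15470 and AGR8A_RS10080 lie higher in every 7 h library.

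**Figure D2:**
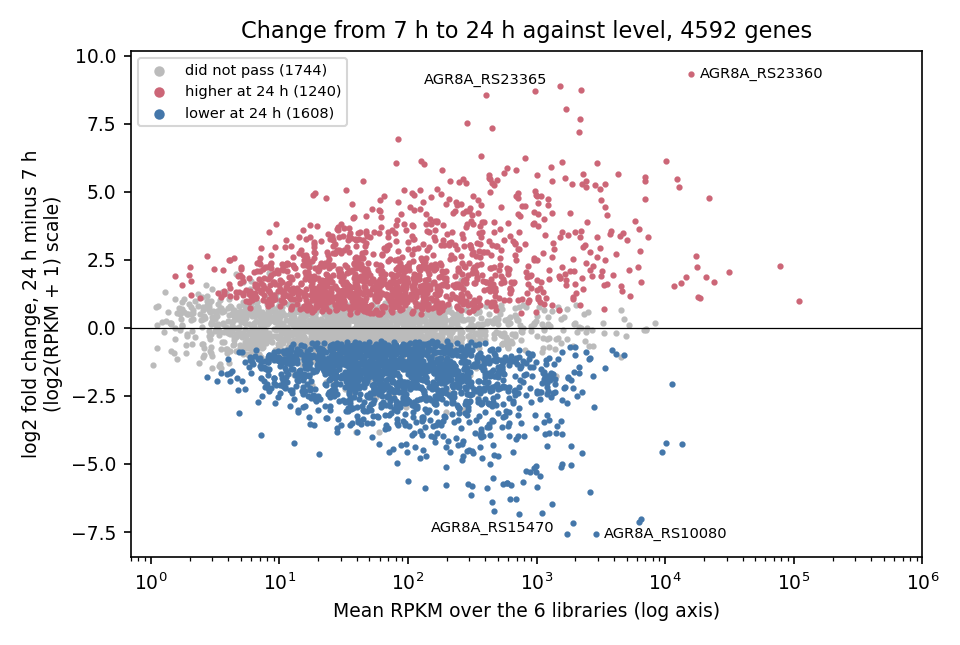
The log2 fold change of each of 4592 genes (24 h minus 7 h) against its mean RPKM over the 6 libraries on a log axis; colours mark genes that passed the test in each direction. Calls of both directions, 1240 higher and 1608 lower, are found over the whole range of levels.

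Genes that changed made up most of the reads at both times. Genes called higher held 13.8% ± 0.60 of the reads at 7 h and 65.0% ± 3.54 at 24 h (SD, n = 3). Genes called lower held 64.0% ± 0.83 at 7 h and 14.5% ± 2.23 at 24 h. The 19 genes with a rise of at least 64-fold went from 0.026% ± 0.002 to 7.87% ± 1.71 of the reads. The 14 genes with a fall of that size went from 5.48% ± 0.66 to 0.047% ± 0.014. Because these sets were chosen by the test itself, the shares describe their weight and are no further evidence of a change.

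The most abundant genes also turned over. Only 4 genes were among the 10 with the highest mean RPKM at both times. Of the 10 highest at 7 h, 6 were lower at 24 h and 4 were higher. These 4 rises became 2 with an equal RPKM sum, 1 with the length trend removed and 0 under quantile normalization. Quantile normalization gives genes of equal rank the same value in every library. It could hardly show a rise of genes that were among the highest at both times, as these 4 were. The 6 falls became 5 with the length trend removed and stayed at 6 under the 3 other scalings. All 10 of the highest at 24 h were called higher there. With an equal RPKM sum 8 of these 10 were, with the length trend removed 6 were, and under quantile normalization 4 were. The limit on quantile normalization holds here too for genes already high at 7 h. The single most abundant gene at both times, of 402 nt, had 73803 ± 5752 RPKM at 7 h and 146275 ± 21296 RPKM at 24 h (SD, n = 3). Its log2 fold change was 0.98 ± 0.30 (SE; limma, adjusted p = 0.023). That call did not hold under every setting, and its adjusted p ranged from 0.0086 to 0.54 over 17 alternatives. The value was 0.43 with an equal RPKM sum (limma, adjusted p = 0.19) and -0.30 under quantile normalization (limma, adjusted p = 0.54). The latter scaling could hardly show a rise, since this gene had the highest mean at 7 h already. Without 7 h replicate 1, 7 h replicate 2 or 24 h replicate 1 it was 1.02, 1.01 and 0.86 and did not pass (limma, adjusted p = 0.072, 0.075 and 0.094).

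Calls were more frequent among abundant genes. Of the 1148 genes with the lowest mean log2 level 46.1% were called, with 299 higher and 230 lower at 24 h. Of the 1148 genes with the highest level 73.0% were called, with 370 higher and 468 lower. Few genes went from no reads to reads: 4 genes had none in any 7 h library and some in every 24 h library, and 2 genes had the reverse.

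Short genes rose more often than long genes. Of 29 genes of up to 80 nt, 19 were higher at 24 h, 3 were lower and 7 did not pass, with a median log2 fold change of 1.98. Whether these genes code for protein was not known, since no product is paired with a tag. Over all lengths, 101 genes had a recovered length that was not a multiple of 3. Of 416 genes over 80 and up to 300 nt, 204 were higher and 58 lower, with a median of 0.89. Of 2100 genes over 600 and up to 1200 nt, 442 were higher and 791 lower, with a median of -0.33. Of 1082 longer genes, 244 were higher and 479 lower, with a median of -0.54. Spearman's rho between length and change was -0.22 across 4592 genes, which are not independent replicates. The order of the classes was the same under quantile normalization. It was also the same with an equal RPKM sum and with median ratios. Those scalings multiply each library by a single factor and shift all genes nearly alike, so they could not test the order. The class over 300 and up to 600 nt had a median of 0.10, which turned to -0.42 with an equal RPKM sum and stayed above 0 under the other scalings. The sum of RPKM was between 1243208 and 1333908 per library at 7 h and between 1776854 and 2025970 at 24 h.

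**Figure D3:**
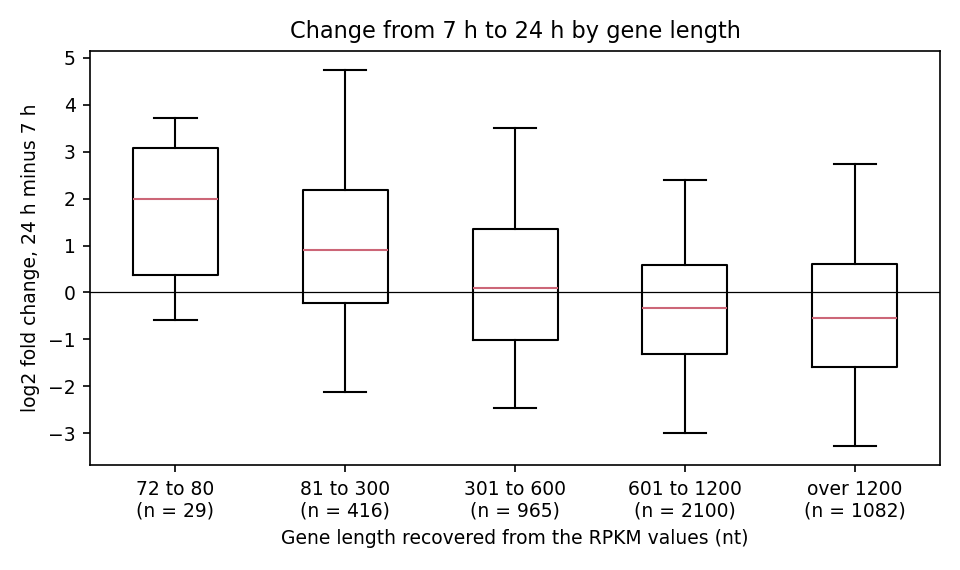
The log2 fold change of 4592 genes (24 h minus 7 h) by gene length in nt; boxes span the quartiles with the median as a line, and whiskers reach the 5th and 95th percentiles. The median falls from 1.98 in the shortest class to -0.54 in the longest.

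Calls of either direction were spread unevenly along the tag numbers, counted in windows of 200 tags. In tags 24005 to 25000, 78 of 126 tested genes were higher and 15 were lower at 24 h. In tags 13005 to 14000, 29 of 197 tested genes were higher and 101 were lower, the most falls in any window, and in tags 14005 to 15000 21 of 145 were higher and 82 were lower. Of the 851 genes with no read in any library, 198 lay in tags 26005 to 27000 and 147 in tags 25005 to 26000, of 200 each. The windows that begin at 23005, 24005, 10005 and 14005 held 76, 74, 64 and 55 of them. These windows were singled out after their values were seen, and no test was run on them.

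**Figure D4:**
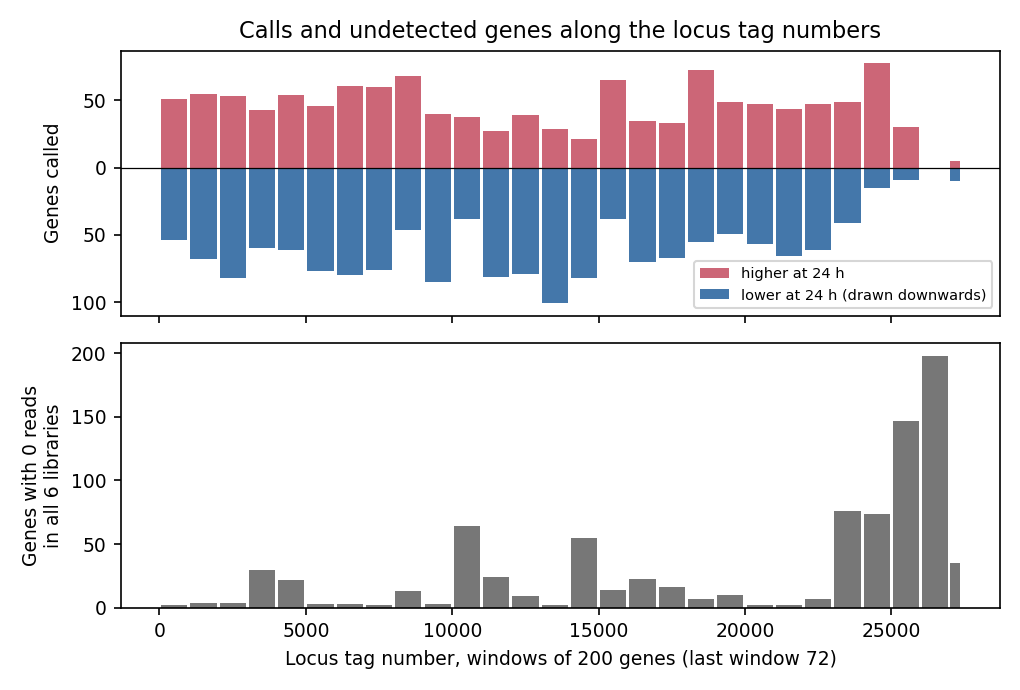
Genes called higher (upwards) and lower (drawn downwards) at 24 h, and genes with 0 reads in all 6 libraries, in windows of 200 consecutive locus tags (the last has 72), by tag number. Rises outnumber falls most clearly in tags 24005 to 25000 (78 against 15), and the bar for undetected genes is highest, at 198, in tags 26005 to 27000.

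Differences between replicates were small beside those between times. Across genes, Pearson's r of log2 levels was 0.93 to 0.97 between 7 h libraries and 0.96 to 0.97 between 24 h libraries, against 0.62 to 0.70 between libraries of different times. The first principal component, with 84.0% of the variance, separated the times. The second, with 7.7%, separated 7 h replicate 3 (-38.4) from 7 h replicates 1 and 2 (23.7 and 13.6). The median SD of a gene between replicates was 0.31 at 7 h and 0.26 at 24 h on the log2 scale. No pair of libraries agreed within sampling noise: for genes with at least 20 reads in a pair, chi-square per gene was between 32.4 and 101 within times, where sampling alone gives about 1. No library was therefore treated as a repeat deposit of another. That the libraries are biological repeats rests on the labels.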

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

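The voom fit and the fit without the length trend were chosen after seeing the data. Under all 17 alternatives the counts of calls, in total and in each direction, with and without the 2-fold limit, stayed within 1.5 times the reported value, and the 4 named tags kept their direction and their call. The rise of the most abundant gene (0.98) kept its call under 11 of the 17, turned to -0.30 under quantile normalization, and did not pass under 5 others. Quantile normalization gives the highest gene of every library the same value, so it could hardly show a rise of this gene. Why the 5 others did not pass was not tested. RPKM as deposited gave 2848 calls. Pseudocounts of 0.1 and 5 RPKM gave 2837 and 2866, no filter gave 2855 of 4621 genes, and a minimum mean of 10 RPKM gave 2688 of 4045. Equal RPKM sums, median ratios and quantiles gave 3087, 2853 and 2867, and shared 2500, 2631 and 2631 of the reported calls in the same direction. Voom on the recovered reads gave 2873 calls and shared 2814. With the length trend removed there were 2835 calls, 2442 of them shared, and 1 reported call turned to the opposite direction. Leaving out each library in turn gave 2525 to 2857 calls, and 2268 to 2403 of at least 2-fold. No pairing by replicate number was seen: deviations of same-numbered libraries correlated at 0.01, -0.01 and -0.05, and no number correlated best with its own. With so few libraries this cannot exclude that the same cultures were sampled at both times. The fit with a replicate block (2725 calls) is given here only. The log2 fold changes of AGR8A_RS23360 ranged from 8.79 to 9.81 over the alternatives, and those of AGR8A_RS15470 from -8.12 to -7.11, with limma adjusted p of at most 6.05e-05 for each. Those of AGR8A_RS23365 ranged from 8.17 to 9.30 (limma, adjusted p at most 6.05e-05). Those of AGR8A_RS10080 ranged from -8.10 to -7.02 (limma, adjusted p at most 0.0001757). Negative binomial tests, the gene list tests and the fits of the curdlan synthesis genes were not run. Of simulated 2-fold changes 85% were called, so smaller changes are missed more often. The simulation was simpler than the data, so that share is not a measured sensitivity.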

Other observations

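The tests on undetected genes and the counts of runs were chosen after the result was seen. Genes with neighbouring tag numbers changed together. Between consecutive tags, Pearson's r of the log2 fold changes was 0.55 over 4481 pairs. It was 0.36 at a distance of 2 tags, 0.17 at 5, 0.06 at 20 and 0.01 at 100. Runs of at least 5 consecutive tags that all rose numbered 42, with 336 genes, against a mean of 4.24 and a maximum of 12 in 1000 shuffles of the calls. Runs that all fell numbered 76, with 547 genes, against a mean of 14.8 and a maximum of 26. The longest rising run held 21 genes with a median log2 fold change of 3.37 and went from 0.0098% ± 0.0019 to 0.46% ± 0.34 of the reads (SD, n = 3). The longest falling run also held 21 genes, with a median of -2.54, and went from 1.22% ± 0.12 to 0.13% ± 0.007. A hypothesis that stays open is that neighbours share transcripts and that tags follow the genome. The fall of r from a distance of 1 to 20 tags was 0.491, which any other local co-regulation would give too.

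Among the 10 splits of the 6 libraries into 3 and 3, only the real one (1 split) gave as many calls, 2848, and the highest other gave 0. The splits are too few for a share under 0.05. Every other split mixed both times in each group, so the difference between times widened the spread within groups. Few calls could arise there, and the 0 is no measure of false calls.

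The 851 genes with no read in any library lay in long runs of consecutive tags. There were 14 runs of at least 10 tags with 695 genes, and the longest had 124. In 1000 shuffles the longest run had 8 tags, and 0 shuffles gave one as long. Transcription at a level that gives a few reads is argued against, since only 54 genes had 1 to 10 reads in total beside 851 with none. That count covers all tags, and levels too low to give a read are not excluded by it. Reads dropped because of near-identical copies stay open: 87.8% of the undetected genes lay in runs of 5 or more tags, but a duplicated region would leave a run too. The genes that flank the 14 runs had a median of 402.5 reads, beside 929 for all detected genes. Another hypothesis that stays open is that the strain lacks these parts of the reference, as in tags 26005 to 27000, where 198 of 200 genes had no read; complete silence of whole regions at both times may also account for it, and no DNA data were used here.

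The rise of short genes may be a property of the cells or of the libraries. For each library, the log2 level relative to the gene's mean over the 6 libraries was fitted on log2 length. The slope was 0.21 to 0.27 in the 7 h libraries and -0.28 to -0.20 in the 24 h libraries. Taking out the gene means makes the slopes of the times opposite in sign, so only their difference carries meaning. The gap between the times, 0.41, exceeded the widest range within a time, 0.075, which argues against bias that varied from library to library regardless of time. The trend was not confined to the most abundant genes: the rank correlation was -0.19 over the 4132 genes left without them and -0.22 over all. A rank correlation weighs all genes alike, so a few abundant short genes could hardly have driven it. Leaving them out was thus a weak test of that explanation. Recovery of short RNA that differed between the times stays open. Between consecutive tags the slope of change on log2 length was -0.341 (95% interval -0.39 to -0.29), beside -0.47 over all genes. The prediction for a gene-by-gene effect, fixed beforehand, asked only for a set part of the slope over all genes, and it was met. The interval leaves out -0.47, so such an effect need not account for the whole trend. A biological rise of short genes would give the same.

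7 h replicate 3 correlated less with the other 7 h libraries (0.93 and 0.94) than they did with each other (0.97). Its lower depth is argued against: thinned to its reads, replicates 1 and 2 still correlated at no less than 0.964 in 20 thinnings, and the highest value with replicate 3 was 0.94. A different length bias is argued against too, since without the length trend its best correlation was 0.943, beside 0.97 for the others. Whether this sample was further along towards the 24 h state stays open. Pearson's r of 7 h replicate 3 with 24 h replicates 1, 2 and 3 was 0.70, 0.69 and 0.65. For 7 h replicate 1 it was 0.67, 0.66 and 0.62, and for 7 h replicate 2 it was 0.69, 0.68 and 0.64. The difference of 7 h replicate 3 from 1 other 7 h library was set against the change from the remaining 7 h library to 24 h. These correlated at 0.141 on average, between the 0.1 and 0.2 set beforehand as limits. The same measure was -0.05 for 7 h replicate 1 and -0.09 for 7 h replicate 2, values that are not independent of that for replicate 3. Without this library 2857 genes were called.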
